A study of Homo sapiens with 3 samples.

How the data were processed

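HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, were profiled on 3 one-colour expression arrays. The series holds 1 array of cells given vehicle, 1 of cells given calcium oxalate monohydrate (COM, 1064 µg/cm2) and 1 of cells given sodium oxalate (NaOx, 4 mM). Per the labels' protocols, cells at 80% confluence spent 24 h without serum and then 24 h with the compound or vehicle, and Cy3-labelled cRNA was made from 0.1 µg of total RNA. Groups were taken from the treatment labels. COM was given per area of dish as crystals and NaOx as a concentration, so the doses differ in kind and could not be matched.

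The deposited files hold the scanner's spot intensities of each array, which per the file headers come from Agilent Feature Extraction with background subtraction, spatial and multiplicative detrending and no scaling between arrays. The version, 12.0.3.1, is given by the submitters' processing notes. The headers name an 8 x 60K gene expression design, whereas a label of the samples names an older cDNA array; the probes in the files are those of the header's design. Each array had 62976 spots, of which 60901 were not controls and carried 58201 different probes. All 3 arrays were on 1 slide and came from 1 scan, so no slide or scan could be compared, and their places on the slide differed with the treatment.

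The processed signal, a background-subtracted linear intensity deposited by the authors, was taken to log2, and the 75th percentile over the non-control spots of the same array was subtracted. Spots with an outlier or non-uniformity flag were left out (81 on the vehicle array, 63 on the COM array and 103 on the NaOx array), and no spot was saturated. Spots of the same probe were averaged. The share of spots well above background was 49.3% on the vehicle array, 51.1% on the COM array and 50.5% on the NaOx array. Of the 25277 probes with an NM accession, 24751 matched a symbol in the RefSeq table of the assembly GRCh38.p14, without versions. In all, 31104 probes (53.4%) had a symbol, for 22439 genes. The probe grid was annotated on an older assembly, so no coordinates are given.

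A gene was represented by the probe with the highest mean log2 signal over the 3 arrays; 6754 genes had several probes. A gene entered a comparison when that probe was well above background on both arrays. A gene whose probes were all not well above background on 1 of the arrays has only a bound. That bound is the bright array's level over the higher of the dim probe's own level and the lowest level of any probe well above background, and is written "at least". It leaves out the error of both levels, and that lowest level is not each probe's own limit of detection. The actual difference can therefore be smaller than the bound. Differences are COM minus vehicle, NaOx minus vehicle and COM minus NaOx on the log2 scale. Near background, subtraction makes log2 differences of dim genes less certain than those of bright genes.

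With 1 array per group there is no replicate, so no test was run and no p-value is given; no difference below has a replicate check, and the number of arrays limits the precision. Technical error was measured on 300 probes spotted 10 times per array, of which 282 were well above background on all arrays. The SD of 1 spot of such a probe was 0.065 on the log2 scale on the vehicle array and 0.068 on the NaOx array. This gives an SD of 0.092 for a COM minus vehicle difference and 0.12 for the dimmest 94 of these probes. The error stated by Feature Extraction for a log2 difference was larger, with a median of 0.20. Neither error includes the differences between cultures or between probes of a gene. Drawing such spot noise 100 times for unchanged genes gave no gene at least 2-fold different in COM vs vehicle and on average 0.01 in NaOx vs vehicle.

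Genes were counted at a difference of 2-fold. The genes named were fixed by rule before the data were examined. In each comparison with vehicle, they are the 12 largest differences in each direction among genes whose brighter array reached that array's median of probes well above background. For COM vs NaOx they are 6 in each direction. Placeholder names were skipped. The 3 largest bounds in each direction and up to 4 members of each gene list with the largest differences were also named. The rule also held genes at least 2-fold different from vehicle in opposite directions, of which there were 0. Other genes are said to have been chosen after their values were seen. A few genes that the rule names are left out of the text.

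The 34 gene lists were likewise fixed before the data were examined, and older symbols were updated through the RefSeq table. For each list with at least 3 measured members, the median difference was set beside the medians of 10000 random lists of the same size. These were drawn within 20 bins of mean signal; drawing with replacement was chosen after seeing the data. The percentile describes these arrays only. A list is called outside the random range below the 2.5th or above the 97.5th percentile, and 5% of random lists fall there. Members at least 1.5-fold different were counted.

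The comparisons with vehicle share 1 control array, which cannot be split. Their correlation across genes was therefore set beside its value in unchanged arrays simulated from spot noise.

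The procedure was tested on simulated data made from the vehicle array with 200 changed genes. In simulated COM vs vehicle data of 14945 genes, 67 of 67 genes changed 2.5-fold and 66 of 66 changed 4-fold passed the 2-fold threshold. Of the 67 changed 1.5-fold, 0% passed. None of the 14745 genes outside these 200 passed. The simulated noise was spot noise of the same size for all genes, and a 2-fold difference is far beyond it. These counts therefore check the calculation, and leave dim genes and differences between cultures untested. The changed genes and the lists below were drawn only from genes above the median signal of those detected on the vehicle array. A list of 20 genes shifted by 0.25 had a recovered median of 0.23 and lay at percentile 100, while 3.5% of 200 random lists lay outside the random range.

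The alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization and scaling by the median of the genes detected on all 3 arrays. The others were no filter on dim probes, a stricter filter, the mean of all probes of a gene, keeping flagged spots, thresholds of 1.5-fold and 4-fold, and random lists not matched on signal. The stricter filter asked for detection on all 3 arrays and a signal above the median on at least 1. Normexp was run on the median spot signal, since the files hold no mean spot signal. Scaling by the 75th percentile of detected probes and by 8 E1A spike-in probes was added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.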

Results

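Gene expression was measured in HEK293T cells after 24 h with vehicle, with crystals of calcium oxalate monohydrate (COM) or with sodium oxalate (NaOx), on 1 array each. Oxalate is the anion that forms calcium oxalate kidney stones, and COM is its common crystal form. NaOx is a soluble salt of the same anion, and whether it stayed dissolved in the culture medium was not measured here. The title of the series names factors of the response to oxalate, and its design text sets COM against vehicle. The 75th percentile of the processed signal was 183.9 on the vehicle array, 158.8 on the COM array and 158.6 on the NaOx array. The number of non-control spots well above background was 30037, 31125 and 30753 in the same order. None of the differences below has a replicate check, and each compares single cultures. Replicate spots of a probe gave a COM minus vehicle difference an SD of 0.092 on the log2 scale, which covers spot noise alone. Different probes of a gene agreed less well. Over 3963 genes, the used probe and the mean of the other measured probes had r = 0.32 in COM vs vehicle. It was 0.51 in NaOx vs vehicle and 0.54 in COM vs NaOx. Only 2 of the genes at least 2-fold different in COM vs vehicle had another measured probe.

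The comparison of COM with vehicle asked what the crystals did to gene expression. DUSP6 (NM_001946), a phosphatase that switches off the kinase ERK, was 6.44-fold higher than on the vehicle array. FOS (NM_005252) and EGR1 (NM_001964), transcription factors switched on within minutes of a growth stimulus, were 6.17-fold and 5.99-fold higher. On the vehicle array, the processed signal was 30.9 for DUSP6, 23.5 for FOS and 59.8 for EGR1. The lowest level well above background there was 7.99. None of these genes had another measured probe. Of 14746 genes measured on both arrays, 39 were at least 2-fold higher and 11 at least 2-fold lower, and 314 and 89 passed 1.5-fold. The SD of the log2 differences over all genes was 0.24, against 0.11 from spot noise alone, and their median was -0.04. The error stated by Feature Extraction for such a difference was closer to that SD, with a median of 0.20.

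Of the 5 genes at least 4-fold higher, the other 2 were too dim for the naming rule, CADPS2 (5.82-fold) and MAFF (4.23-fold), named after their values were seen. Among genes bright enough for that rule, the next differences were in genes of varied function. RHEBL1, a small GTPase of the Rheb family, was 3.27-fold higher. SLC2A14, a glucose transporter and close paralog of another, was 2.65-fold higher, C11orf96 2.62-fold and PHLDA2, an imprinted gene, 2.07-fold. Close to the threshold were NUPR1, a stress-induced chromatin protein (1.99-fold), VGF, a neuropeptide precursor (1.98-fold), and MALAT1, an abundant nuclear long non-coding RNA (1.95-fold). PLAU, the urokinase protease, was 1.85-fold higher and ZCCHC12 1.83-fold. The other 3 probes of MALAT1 gave log2 differences from 0.34 to 0.62 beside 0.96 for the named probe.

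Among genes bright enough for the naming rule, those lower on the COM array differed less. IST1, an ESCRT protein, was 1.66-fold lower, DDX24, an RNA helicase, 1.64-fold and TRAP1, a mitochondrial chaperone, 1.60-fold. FAM27E2, a non-coding RNA, was 1.57-fold lower, and ABCD3, a peroxisomal transporter, 1.56-fold. NOL6 and RRP1, both nucleolar proteins of ribosome assembly, were 1.55-fold and 1.5-fold lower. PGS1 (1.54-fold), ZSWIM5 (1.53-fold), ATP1A4 (1.5-fold), DLGAP2 (1.5-fold) and TCAIM (1.49-fold) complete the group. A second probe of ABCD3 gave -0.09 and one of TCAIM 0.02, so their probes disagreed; the second probe of NOL6 gave -0.77. Among genes not well above background on the vehicle array, ETV4, an ERK-responsive transcription factor, was at least 9.22-fold higher with COM. PKP1, a desmosome protein, was at least 9.09-fold and ADRA2A, an adrenergic receptor, at least 6.91-fold higher. Among those not well above background on the COM array, FAM83C-AS1 was at least 4.15-fold, MIR3976HG at least 4.08-fold and TRPC4 at least 3.78-fold lower.

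By gene list, the immediate early genes led. Their 15 measured members had a median of 0.49, at percentile 100 of the random lists, with 11 above 0 and 4 below; 6 were at least 1.5-fold higher and 0 lower. DUSP5 stood at 0.86. Less the median of all genes, the median of the immediate early list lay between 0.27 and 0.54 over the alternatives. The hypoxia and glycolysis list had a median of 0.16 (percentile 100), with ANKRD37 at 0.77, ENO2 at 0.76 and EGLN3 at -0.35. Genes of the ATF4 amino acid and integrated stress response had a median of 0.10 (percentile 100). It was -0.03 under spike-in scaling, which moves every gene alike and puts the median of all genes at -0.17. In that list NUPR1 at 0.99 and DDIT3 at 0.80 were the 2 of 20 members past 1.5-fold. The ribosomal proteins had a median of 0.08 (percentile 99.98), the replication-dependent histones 0.06 (percentile 98.0) and the unfolded protein response genes 0.05 (percentile 98.9). With 8 histones of 10 above 0 and the largest at 0.20 (H1-2), none of these members reached 1.5-fold. Under spike-in scaling the medians of these 3 lists were -0.05, -0.08 and -0.08, by the same shift of all genes, and no list crossed the edge of the random range with that scaling. The ribosomal median was -0.01 after quantile normalization. These 3 lists and ribosome biogenesis lay inside the range under at least 1 other alternative.

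Lists below the random range on the COM array had small medians and no member past 1.5-fold. Cholesterol synthesis stood at -0.18 (percentile 0.42), with MSMO1 at -0.42. S phase and DNA replication stood at -0.16 (percentile 0.52), with UHRF1 at -0.39 and 17 of 18 members below 0. Nuclear-encoded oxidative phosphorylation stood at -0.14 (percentile 0.71), and ribosome biogenesis at -0.14 (percentile 1.92), with UBTF and PES1 at -0.56. In all, 6 lists lay above and 4 below the random range, where 1.65 of 33 lists of randomly drawn genes would be expected outside it. Genes of a list can vary together between cultures, and some lists share members. The number expected without a treatment effect is therefore not known.

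The lists closest to the question of crystals and kidney cells lay inside the range in the main setting. Many of their members had no value. Measured were 12 of 21 crystal-binding, 8 of 16 oxalate handling, 11 of 18 kidney injury and 11 of 23 NF-kB genes. The crystal-binding and stone matrix proteins had a median of 0.01 (percentile 78.1), with ANXA1 at 0.69 and CD44 at -0.34; the median reached -0.13 under spike-in scaling. Oxalate handling stood at -0.06 (percentile 46.5), with SLC26A2 at -0.07 and GRHPR at -0.13. Kidney injury markers stood at 0.07 (percentile 94.97), with TIMP1 at 0.62 and IGFBP7 at -0.46, and at -0.06 under spike-in scaling; they lay above the range after quantile normalization, without the filter on dim probes and with the strict filter. Reactive oxygen genes stood at -0.07 (percentile 40.5), with PRDX2 at -0.41, and the NRF2 antioxidant genes at -0.05 (percentile 54.4), with GCLM at 0.28. The NRF2 median was 0.01 when scaled by the percentile of detected probes. NF-kB inflammatory genes had a median of 0.22 (percentile 96.7), with CXCL1 at 0.72, and lay above the range without the filter and against unmatched lists.

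The counts are the least stable part of this comparison. Spike-in scaling gave 23 genes at least 2-fold higher and 24 lower (48.9% higher, against 78% in the main setting), and quantile normalization gave 53.1% higher. Normexp gave 6 higher and 0 lower, and the strict filter 5 and 0.

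The comparison of NaOx with vehicle asked the same of sodium oxalate. Genes of cholesterol synthesis were lower together on the NaOx array, by 2.57-fold at the list median. INSIG1 (NM_005542), which retains the sterol sensor complex in the endoplasmic reticulum, was 7.99-fold lower. IDI1, an enzyme of isoprenoid synthesis, was 4.88-fold and MSMO1, a sterol oxidase, 4.66-fold lower. On the same array NUPR1 was 16.8-fold higher, GDF15, a stress cytokine and p53 target, 5.93-fold, FOS 7.20-fold and EGR1 5.97-fold. Of 14665 measured genes, 379 were at least 2-fold higher and 165 at least 2-fold lower, and 37 and 6 passed 4-fold. The SD of the log2 differences was 0.45, against 0.24 in COM vs vehicle, with a median of -0.02.

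Among genes bright enough for the naming rule, the largest difference was that of FUT1 (NM_000148), a fucosyltransferase, at 17.5-fold higher. INHBA, the activin A subunit, was 16.5-fold, S100P, a calcium-binding protein, 12.2-fold, the antisense RNA VLDLR-AS1 10.5-fold and the keratin-associated KRTAP19-1 9.48-fold higher. TMEM71 (5.86-fold), SH2D3C (5.68-fold) and CD86, a costimulatory ligand (5.42-fold), followed. On the vehicle array, INHBA had a processed signal of 10.6, S100P 15.5 and VLDLR-AS1 16.2, close to the lowest level well above background (7.99). Their folds are therefore less certain than that of NUPR1 (234.0).

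Among the 12 lowest of the genes bright enough for the naming rule, SQLE (3.40-fold), HMGCS1 (3.21-fold) and DHCR7 (2.83-fold) are further enzymes of sterol synthesis. NOG, a BMP antagonist, was 3.57-fold lower, and HOXA13, a homeobox factor, 3.22-fold. PCYT2, an enzyme of phosphatidylethanolamine synthesis, was 3.05-fold, PLA2G4A, a phospholipase, 2.85-fold and LRATD2 2.79-fold lower. The 2 other probes of PCYT2 gave log2 differences of -1.87 and -0.33, so its probes disagreed. Genes not well above background on the vehicle array included ELSPBP1, at least 16.9-fold higher with NaOx, UTS2, at least 12-fold, and LINC01564, at least 9.43-fold. Genes not well above background on the NaOx array included FGFBP1, at least 5.99-fold lower, and FAM83C-AS1, at least 3.88-fold.

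The cholesterol synthesis and SREBP2 list had a median of -1.36 over 18 members, at percentile 0 of the random lists. All 18 were lower and 17 were at least 1.5-fold lower; SC5D, at -0.26, was the exception and is named after its value was seen. The 18 measured p53 targets were all higher, with a median of 0.86 (percentile 100) and 11 at least 1.5-fold higher. Less the median of all genes, the p53 median lay between 0.46 and 1.01 over the alternatives. GDF15 stood at 2.57, TP53I3 at 1.67, PHLDA3 at 1.5 and CDKN1A, the cell cycle inhibitor p21, at 1.33. The ATF4 list had a median of 0.62 (percentile 100), with 11 of 20 members at least 1.5-fold higher and 0 lower. Its leading members were NUPR1 at 4.07, CHAC1 at 1.79, DDIT3 at 1.54 and ATF3 at 1.49.

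Further lists lay above the random range. NF-kB genes had a median of 0.83 (percentile 99.98), with LIF at 1.71, RELB at 1.41 and CXCL1 at 1.28, over 11 measured members of 23 on the array. Without the filter on dim probes, that median was 0.15 above that of all genes and inside the range. Immediate early genes had a median of 0.44 (percentile 99.99), with 5 of 15 at least 1.5-fold higher and MYC, at -1.14, the 1 that was lower by as much. Less the median of all genes, their median lay between 0.26 and 0.51 over the alternatives. The histones had a median of 0.45 (percentile 100), and all 10 were above 0, up to 0.64 for H2BC12. Kidney injury markers stood at 0.31 (percentile 99.6), with CDKN1A at 1.33, CCN1 at 1.21 and SOX9 at -1.10. The NFAT5 solute response stood at 0.25 (percentile 99.0), with PRSS8 at 1.27. The ribosomal proteins stood at 0.11 (percentile 99.9) and the apoptosis regulators at 0.14 (percentile 97.54), with CASP8 at 0.93 and BMF at -0.86.

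Below the range, besides cholesterol synthesis, were lists that included those of glycolysis and of reactive oxygen detoxification and production. Hypoxia and glycolysis stood at -0.37 (percentile 0), with EGLN3 at -1.12, ANKRD37 at -0.86, ENO2 at 0.95 and VEGFA at 0.79. Reactive oxygen detoxification and production, which holds genes of both kinds, stood at -0.39 (percentile 0.07). All 13 members were below 0, with GPX3 at -0.71, CYBA at -0.66 and catalase (CAT) at -0.58. The heat shock list stood at -0.28 (percentile 0.82), with HSP90AB1 at -1.24 and HSPA1B at -0.88. Ribosome biogenesis stood at -0.25 (percentile 1.03), with PES1 at -0.62, and calcium handling at -0.24 (percentile 1.37), with ATP2A3 at -1.18. Calcium handling lay inside the range with normexp, quantile normalization and the strict filter, where its median was -0.0094 relative to all genes. Heat shock, kidney injury, NFAT5, apoptosis and ribosomal protein lists also lay inside under at least 1 alternative. The 4 measured fibroblast markers stood at -0.61 (percentile 0.67), with LUM at -2.24 and PDGFRB at 0.68. In all, 9 lists lay above and 7 below the range, where 1.65 of 33 lists of randomly drawn genes would be expected outside. As with COM, the number expected without a treatment effect is not known.

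Several lists closest to the treatment lay inside the range, with 8 of 16 oxalate handling and 12 of 21 crystal-binding genes measured. The NRF2 list stood at -0.16 (percentile 16.4), with HMOX1 at -1.35 and ABCC2 at 0.65. Oxalate handling stood at -0.28 (percentile 3.71), with SLC26A6, an oxalate exchanger, at -0.85 and LDHA at -0.63; it lay below the range after quantile normalization and with the mean of all probes, where it was -0.57 relative to all genes. The crystal-binding list stood at -0.15 (percentile 18.5), with CD44 at 1.09 and ANXA1 at 0.90. Fibrosis and epithelial-mesenchymal transition stood at -0.19 (percentile 5.27), with ACTA2 at 2.29, MMP9 at 1.48, CDH1 at -1.27 and COL1A1 at -0.82. The mean of that list was 0.06, of opposite sign to its median. Housekeeping genes stood at -0.19 (percentile 10.4), with ACTB at -0.53 and GAPDH at -0.41.

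Normexp gave 73 genes at least 2-fold higher and 43 lower, and the strict filter 77 and 46. Normexp also left CDKN1A at 0.47 and ATP2A3 at 0.01.

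**Figure D1:**
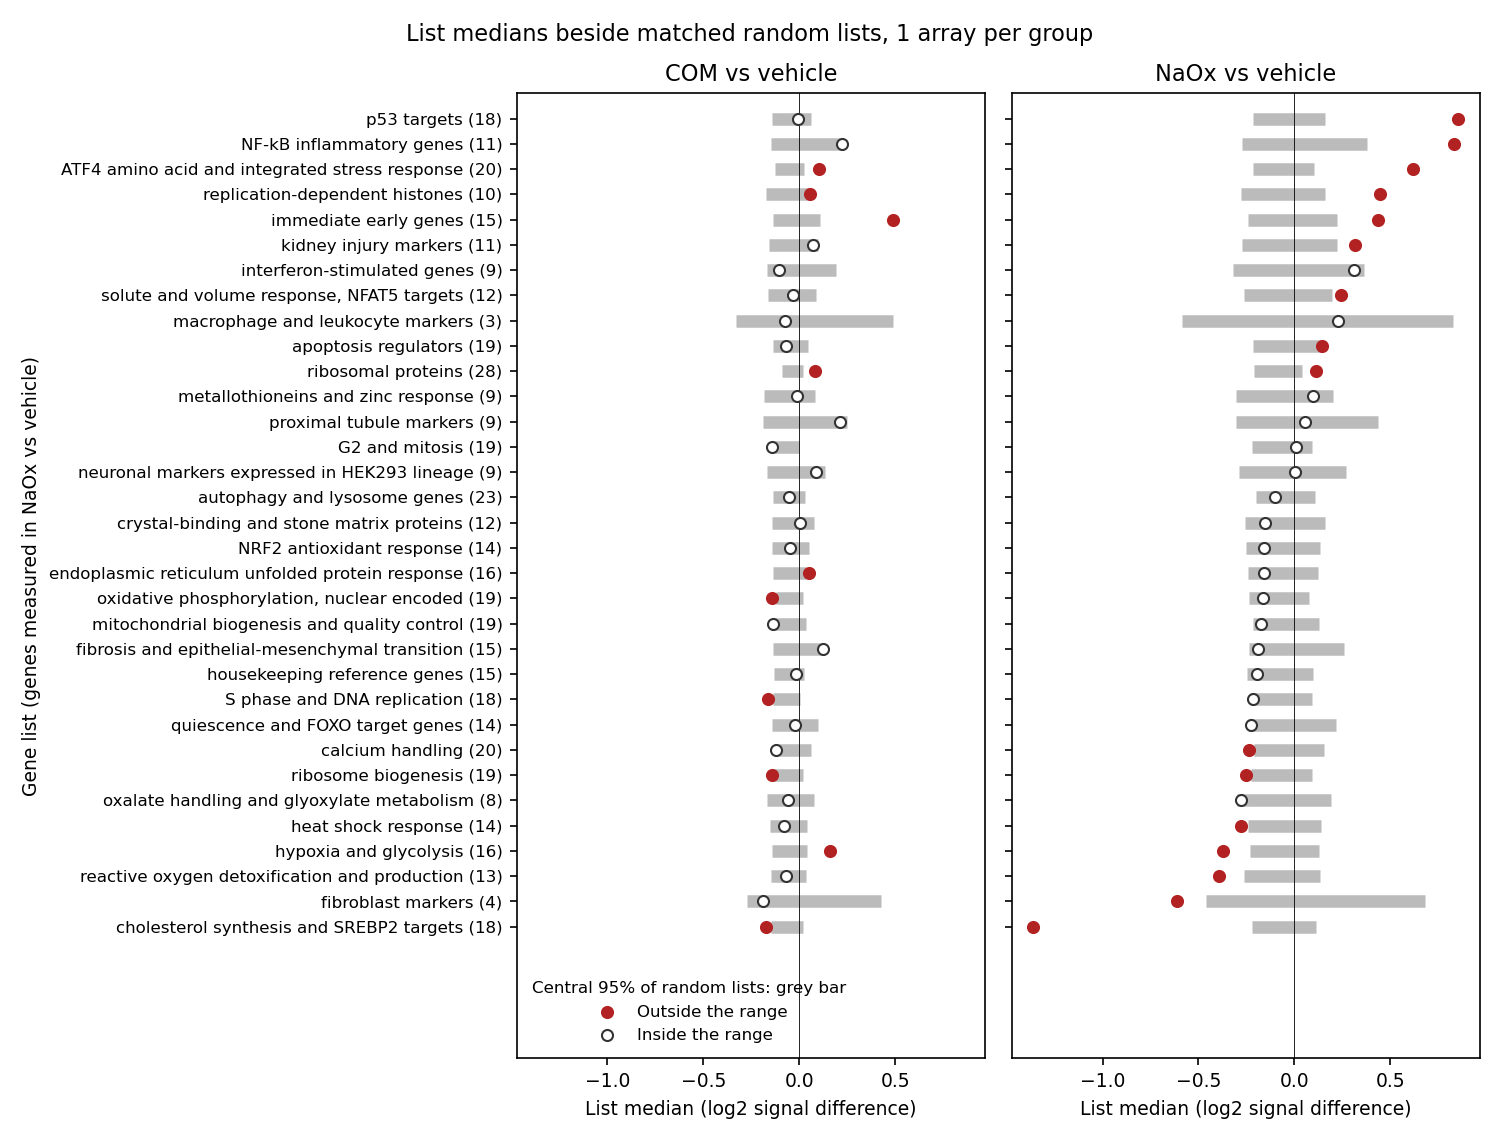
Medians of 33 gene lists in COM vs vehicle (left) and NaOx vs vehicle (right), as log2 signal differences of single arrays. Grey bars span the central 95% of 10000 random lists matched on signal, filled points lie outside and open points inside them; cholesterol synthesis (-0.18 and -1.36) and p53 targets (-0.01 and 0.86) are far apart between the panels.

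The direct comparison of COM with NaOx set the crystals beside sodium oxalate, at doses that differ and at the same 24 h. It does not use the vehicle array. Cholesterol synthesis genes were higher on the COM array, with a list median of 1.13 (percentile 100) and all 18 members above 0. INSIG1 was 8.76-fold and IDI1 4.49-fold higher with COM. DUSP6 was 3.93-fold, NOG 3.76-fold and HOXA13 3.48-fold higher. Lower on the COM array were NUPR1 (8.46-fold), INPP5D, an inositol phosphatase of blood cells (6.27-fold), VLDLR-AS1 (6.13-fold), S100P (5.64-fold), KRTAP19-1 (5.57-fold) and FUT1 (5.14-fold). Of 14849 measured genes, 165 were at least 2-fold higher and 281 at least 2-fold lower with COM, and the SD of the differences was 0.41. Bounds were largest for PKP1 (at least 9.37-fold), CADPS2 (at least 8.07-fold) and ADRA2A (at least 7.12-fold), higher with COM. Lower with COM were UTS2 (at least 13.2-fold), NECTIN4 (at least 11-fold) and GDAP1L1 (at least 9.91-fold).

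Of the 14 lists outside the random range, the unfolded protein response, G2 and mitosis and autophagy lists lay inside it in NaOx vs vehicle, and the other lists outside in both. The p53 targets had a median of -0.72 (percentile 0), with all 18 lower on the COM array. The ATF4 list stood at -0.61 (percentile 0) and NF-kB genes at -0.61 (percentile 0.03). Without the filter on dim probes the NF-kB median was -0.12 relative to all genes, still below the range. The histones stood at -0.36 (percentile 0.03) and apoptosis regulators at -0.17 (percentile 1.92). The hypoxia and glycolysis list stood at 0.43 (percentile 100). The list of reactive oxygen detoxification and production stood at 0.21 (percentile 99.2) and the unfolded protein response at 0.23 (percentile 99.8). G2 and mitosis genes stood at -0.20 (percentile 0.22), with 17 of 19 lower on the COM array and none by 1.5-fold. Their medians against vehicle were -0.14 with COM (percentile 3.05) and 0.01 with NaOx (percentile 83.5), the latter -0.02 under spike-in scaling. Immediate early genes had a median of 0.00 (percentile 49.9), with DUSP6 at 1.98 and CCN1 at -0.85, and -0.10 under spike-in scaling. Heat shock (0.19, percentile 97.8), autophagy and lysosome (0.13, percentile 97.6), fibroblast markers (0.48, percentile 97.52) and ribosomal proteins (-0.04, percentile 1.93) lay at the edge of the range. Of these, heat shock, autophagy and ribosomal proteins, and also apoptosis regulators, lay inside it under at least 1 alternative. Spike-in scaling gave 22.9% of the 2-fold genes as higher, against 37% in the main setting, and the strict filter gave 37 higher and 51 lower.

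The genes that stood out in both comparisons with vehicle overlapped in part. Among 14592 genes measured on all arrays, 34 were at least 2-fold higher with COM and 375 with NaOx, and 17 with both. They included FOS, EGR1, FUT1, INHBA, S100P, C11orf96, RHEBL1 and TMEM71. For genes at least 2-fold lower, 2 were shared of 10 and 165, and 0 genes were 2-fold different in opposite directions. Both comparisons use the same vehicle array, so these overlaps have no value for unchanged cultures to stand beside. Across genes, which are not independent replicates, Pearson's r of the COM and NaOx differences was 0.44 and Spearman's rho 0.41. Unchanged arrays simulated from spot noise gave r = 0.52. The covariance was 0.048 against 0.0068 in the simulation. The simulation leaves out differences between cultures, so how much of the excess comes from the shared array is not known.

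**Figure D2:**
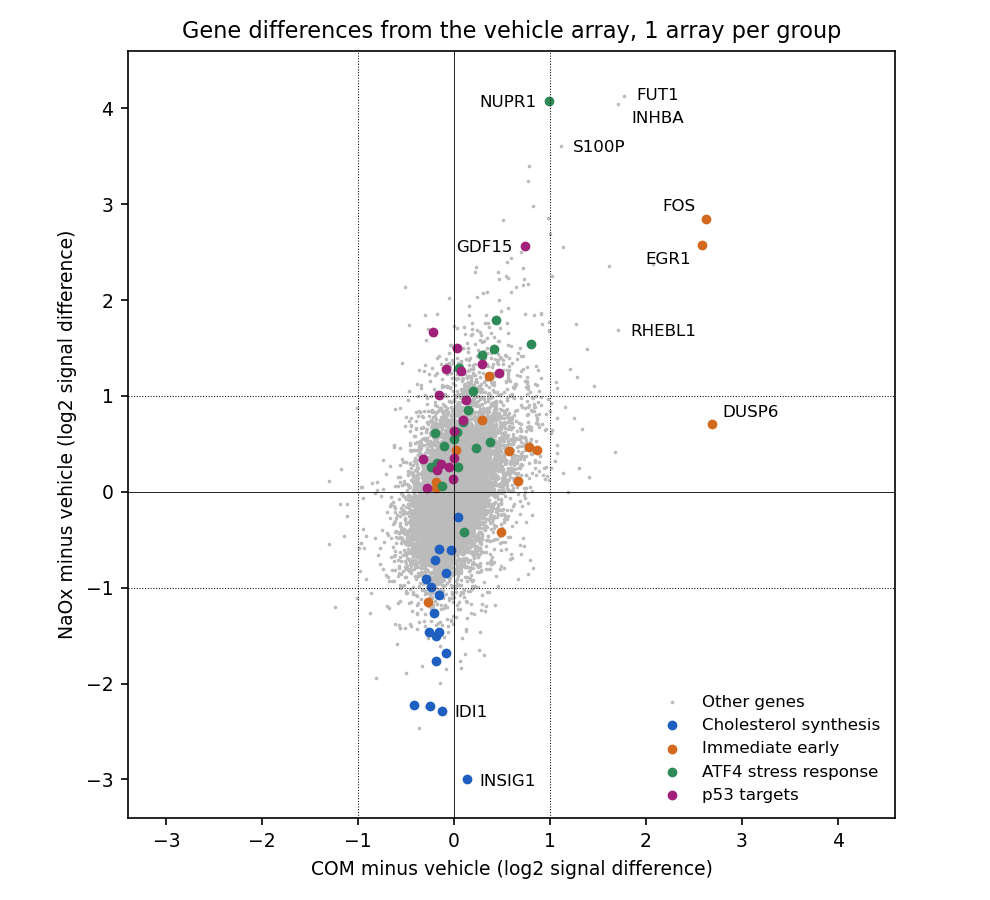
Log2 signal difference from vehicle with COM (horizontal) and NaOx (vertical) for genes measured on all 3 arrays, with members of 4 gene lists in colour and dotted lines at 2-fold. FOS (2.62 and 2.85) and EGR1 (2.58 and 2.58) are high on both axes, DUSP6 (2.69 and 0.71) mainly with COM, and the cholesterol synthesis genes are low with NaOx, down to -3.0 for INSIG1.

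**Figure D3:**
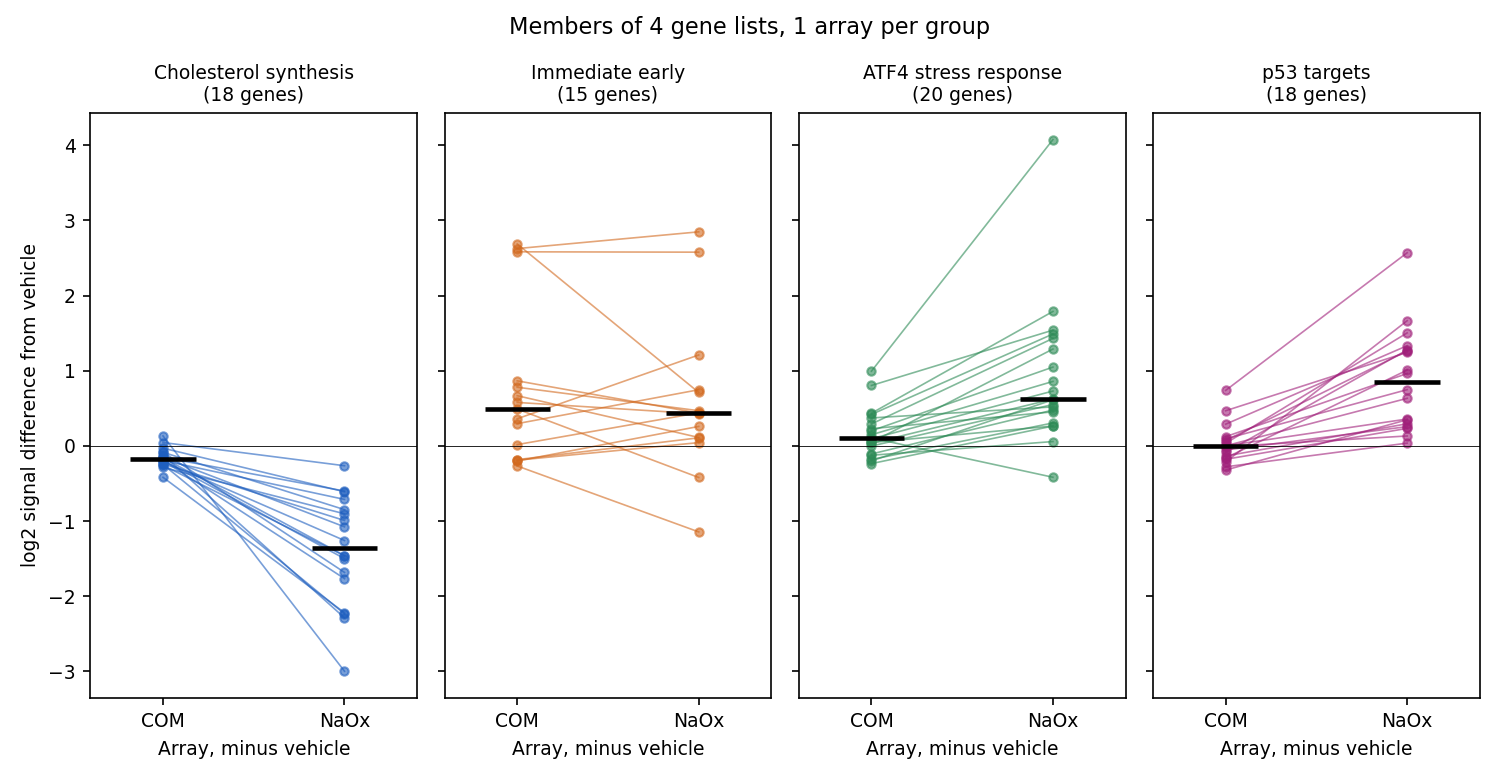
Log2 signal difference from vehicle of each member of 4 gene lists on the COM and NaOx arrays; lines join the values of a gene and black bars are medians over the genes measured against vehicle on both. The cholesterol synthesis medians are -0.18 and -1.36, the immediate early medians 0.49 and 0.44, the ATF4 medians 0.10 and 0.62 and the p53 medians -0.01 and 0.86.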

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

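No test in this part was run, and the differences between the treatments given here were not tested. The hypoxia and glycolysis list differed in direction between the treatments: its median was 0.16 in COM vs vehicle and -0.37 in NaOx vs vehicle. With 1 array per group, every array of each treatment moved its own way by construction. Of the 16 measured members, 12 were above 0 with COM and 13 below 0 with NaOx. ANKRD37 stood at 0.77 and -0.86, PDK1 at 0.17 and -0.58, and HK2 at 0.11 and -0.72, while ENO2 stood at 0.76 and 0.95; PDK1 and HK2 were chosen after their values were seen.

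Probes without a RefSeq symbol, which enter no comparison in the results, also differed between the arrays. In COM vs vehicle, 43 of 7082 such probes well above background (0.607%) were at least 2-fold higher and 8 at least 2-fold lower. In NaOx vs vehicle, 242 of 6893 (3.51%) were higher and 98 (1.42%) lower.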

How the results depend on the processing

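The tests chosen after the results were seen are scaling by the 75th percentile of detected probes and by spike-ins, and the reading of list medians less the median of all genes. No paired analysis was possible because each group has 1 array. Signal over background limits which genes have a value: 480 genes higher and 187 lower with COM, and 544 and 265 with NaOx, have only a bound. The vehicle array had the fewest spots well above background. Its lowest such level was 7.99, against 6.27 on the COM array and 6.68 on the NaOx array. How far this gave the excess of higher genes among the bounds was not tested. Of 96 named gene values of at least 2-fold, 31 were below 2-fold under at least 1 of the 9 alternatives where they had a value, and 7 of them under one other than normexp, which adds 50 to every signal. The value that changed sign was that of ATP2A3 in NaOx vs vehicle, at 0.0061 with normexp. Spike-in scaling moved the median of all genes to -0.17 in COM vs vehicle and -0.11 in COM vs NaOx, so list medians are given below less the median of all genes in the same setting. Of the lists outside the random range, 6 of 10 in COM vs vehicle, 9 of 16 in NaOx vs vehicle and 10 of 14 in COM vs NaOx stayed outside under each of the 9 recomputing settings that gave them a value. The strict filter left too few members for the fibroblast, fibrosis, interferon, leukocyte and proximal tubule lists, and gave a value for 254 of the 432 named gene values. Cholesterol synthesis, the ATF4 response and hypoxia and glycolysis did so in all 3 comparisons, immediate early genes in both with vehicle, and p53 targets in both with NaOx. Except for settings that change which genes are measured or which threshold applies, the cause of the moves below was not tested.

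Counts of genes at least 2-fold higher and lower moved by over 1.5 times as follows, in the order COM vs vehicle, NaOx vs vehicle and COM vs NaOx. Normexp gave 6 and 0, 73 and 43, and 33 and 48. No filter on dim probes gave 772 and 470, 1311 and 693, and 845 and 1062; the strict filter gave 5 and 0, 77 and 46, and 37 and 51. A 1.5-fold threshold gave 314 and 89, 1164 and 940, and 764 and 1011, and a 4-fold threshold 5 and 0, 37 and 6, and 5 and 21. In COM vs vehicle, spike-in scaling gave 23 and 24, and quantile normalization 23 lower. The SD of the log2 differences was 0.32 in NaOx vs vehicle and 0.27 in COM vs NaOx with normexp, and 0.47, 0.59 and 0.57 without the filter. The correlation across genes was 0.52 with normexp and lay between 0.40 and 0.52 over all 9 settings.

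The following lists moved inside the random range. With normexp they were histones (0.041) and ribosome biogenesis (-0.11) in COM vs vehicle, apoptosis regulators (0.080) and calcium handling (-0.15) in NaOx vs vehicle, and apoptosis regulators (-0.11) in COM vs NaOx. After quantile normalization they were ribosomal proteins (0.0034) in COM vs vehicle, apoptosis regulators (0.17), calcium handling (-0.17) and ribosomal proteins (0.061) in NaOx vs vehicle, and apoptosis regulators (-0.15) and ribosomal proteins (-0.054) in COM vs NaOx. Without the filter they were heat shock (-0.18), NF-kB (0.15), apoptosis regulators (0.20), kidney injury markers (0.12) and NFAT5 targets (0.26) in NaOx vs vehicle. In COM vs NaOx they were autophagy (0.19) and ribosomal proteins (0.023, percentile 3.6). The ribosomal value changed sign relative to all genes, whose own median moved from -0.0068 to -0.060. With the strict filter they were histones (0.11) in COM vs vehicle, calcium handling (-0.0094) and NFAT5 targets (0.24) in NaOx vs vehicle, and autophagy (0.099) and ribosomal proteins (-0.030) in COM vs NaOx. With the mean of all probes they were the unfolded protein response (0.050) in COM vs vehicle, and heat shock (0.16), autophagy (0.057) and ribosomal proteins (-0.030) in COM vs NaOx. With outlier and non-uniform spots kept, apoptosis regulators (0.15) moved inside in NaOx vs vehicle. Against random lists not matched on signal, 32 of the 40 list medians outside the range stayed outside. Those inside were the unfolded protein response (0.090) and histones (0.094) in COM vs vehicle, apoptosis regulators (0.17) and ribosomal proteins (0.14) in NaOx vs vehicle, and heat shock (0.20), apoptosis regulators (-0.16), autophagy (0.14) and ribosomal proteins (-0.030) in COM vs NaOx.

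The following lists moved outside the range. In COM vs vehicle these were mitosis (-0.17) and proximal tubule markers (0.21) with normexp, and kidney injury markers after quantile normalization (0.16) and with the strict filter (0.17). Without the filter they were NF-kB (0.19), mitosis (-0.069), mitochondrial biogenesis (-0.061) and kidney injury markers (0.11). With the mean of probes they were apoptosis regulators (0.091) and NFAT5 targets (0.13), and against unmatched lists NF-kB (0.26), mitosis (-0.11), fibrosis (0.16) and proximal tubule markers (0.25). In NaOx vs vehicle they were interferon genes with normexp (0.27) and against unmatched lists (0.34), oxalate handling after quantile normalization (-0.28) and with the mean of probes (-0.57), S phase genes with the mean of probes (-0.26) and FOXO targets without the filter (-0.18). In COM vs NaOx they were FOXO targets with normexp (0.13) and without the filter (0.27), and crystal-binding proteins with the strict filter (0.23). With the mean of probes they were oxalate handling (0.41), kidney injury markers (-0.25) and NFAT5 targets (-0.20).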

Other observations

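In this part, the tests of single probes or spots and of the vehicle array, and the readings of the LXR and ERK lists, were chosen after the results were seen. The G2 and mitosis and mitochondrial biogenesis genes came close to the edge of the random range in COM vs vehicle. All 19 measured mitosis genes were below 0 there, with KIF20A at -0.44 as the lowest and none at 1.5-fold. Mitochondrial biogenesis stood at -0.14 with COM (percentile 2.73), with TFB2M at -0.40, and at -0.17 with NaOx (percentile 7.50), with UCP2 at -1.23 and PPARGC1A at -0.84. S phase genes stood at -0.21 with NaOx (percentile 3.81), with CCNE1 at -0.85 and UHRF1 at -0.62, and oxidative phosphorylation at -0.16 (percentile 18.0), with ATP5F1B at -0.63. The unfolded protein response stood at -0.16 with NaOx (percentile 13.4), with XBP1 at 0.69 and SDF2L1 at -0.69. Interferon-stimulated genes stood at -0.10 with COM (percentile 10.9) and 0.31 with NaOx (percentile 96.0), with IRF7 at 0.75 and IFIT1 at -0.69 on the NaOx array. Quiescence and FOXO targets stood at -0.23 with NaOx (percentile 3.19), with KLF2 at 0.84, CCND1 at -0.79 and GAS1 at -0.75. Metallothioneins stood at 0.10 with NaOx (percentile 88.2), with MT1F at 1.42 and the zinc transporter SLC39A10 at -1.15.

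Markers of other cell types gave no common direction. With COM, the proximal tubule markers stood at 0.21 (percentile 95.2), with PAX2 at 0.52 and LRP2 at -0.30. With NaOx they stood at 0.05 (percentile 51.5; -0.08 after quantile normalization), with LRP2 at -0.82 and a mean of -0.06. The 3 measured leukocyte markers stood at -0.07 with COM (percentile 24.2; mean 0.0064) and 0.23 with NaOx (percentile 70.0), with CD14 at 0.63. The neuronal genes, which this line expresses, stood at 0.09 with COM (percentile 92.8; -0.04 under spike-in scaling). With NaOx they stood at 0.0021 (percentile 57.3; -0.03 under spike-in scaling), with INA at 1.69, SNAP25 at 1.11 and GAP43 at -0.87. The fibroblast markers stood at -0.19 with COM (percentile 7.18). Of the inflammasome list only NEK7 and TXNIP were measured, so it has no median; NEK7 stood at 0.51 with COM and TXNIP at 0.68 with NaOx.

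The remaining lists of COM vs vehicle lay inside the range in the main setting. Fibrosis stood at 0.12 (percentile 96.7; -0.01 under spike-in scaling), with TGFB1 at 0.61, and calcium handling at -0.12 (percentile 4.48), with ATP2A3 at -0.38. Heat shock stood at -0.08 (percentile 31.4), with HSP90AB1 at -0.44, and apoptosis regulators at -0.07 (percentile 31.9), with BIK at 0.92, BCL2 at 0.60, a mean of 0.08 and a median of 0.0058 after quantile normalization. The medians of 5 further lists changed sign with the scaling, but a single factor per array moves every gene alike, and no list crossed the edge of the random range under such a scaling. These were p53 targets at -0.01 (percentile 75.9), autophagy at -0.05 (percentile 54.0), metallothioneins at -0.01 (percentile 74.8), NFAT5 targets at -0.03 (percentile 59.1) and FOXO targets at -0.02 (percentile 54.4). The means of p53 targets (0.02), autophagy (0.0059) and NFAT5 targets (0.04) were above 0. Housekeeping genes stood at -0.02 (percentile 82.3), with TFRC at 0.25, and changed sign too. Autophagy stood at -0.10 with NaOx (percentile 24.2), with GPNMB at 0.84 and GLA at -0.71.

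Cholesterol synthesis genes were lower together on the NaOx array. Of the members, 94.4% (17 of 18), each on its own probe, were at least 1.5-fold lower. With the list median already past 1.5-fold, a large share was bound to follow. It is therefore no separate test of an error of single probes or spots. The 1 other measured probe of a member was also lower, at -0.76. A vehicle array that stands apart is argued against by the median of 1.13 in COM vs NaOx, which leaves that array out, and a brightness-dependent difference by a median of -1.29 after quantile normalization. The fatty acid synthesis list stood at -0.68 (percentile 0), with 8 of 10 members lower and 5 at least 1.5-fold lower, and at -0.20 with COM (percentile 0.56), so a candidate explanation is a difference that covers SREBP targets of both kinds, though FADS1 (0.09) and FADS2 (0.39), chosen after their values were seen, were not lower with NaOx. Whether sterol surplus lay behind it stays open: LXR targets stood at percentile 13.2, but 2 of 6 were higher and 4 lower, so the bound set in advance, below the 50th percentile, was judged too lenient once the value was seen.

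The immediate early list had a higher median on both oxalate arrays, with 11 of 15 members higher with COM and 13 of 15 with NaOx. With COM, 40% of the members (6 of 15), each on its own probe, were at least 1.5-fold higher, against 2.13% of all genes. With NaOx it was 5 of 15, with 1 lower by as much, against 7.94% of all genes. The shares of all genes are not matched on signal, and the members' values are those that gave the list its median. These shares are therefore no separate test of an error of single probes or spots. Only 2 members had another measured probe, and both of these probes were higher, with a median of 0.37. A vehicle array that stands apart cannot be told apart from an effect of both treatments, since the median in COM vs NaOx was 0.0048, as either would give. Whether ERK output was higher with COM than with vehicle stays open. ERK feedback genes, with DUSP6 and SPRY2 left out since their values had been seen when the list was written, stood at percentile 30.6. This is below the 50 set in advance as counting against it. Of 11 measured members, 7 were lower, down to -0.55 for SPRY4, and 3 were at least 1.5-fold higher. Among those 3, MAFF was also 5.21-fold higher with NaOx. ETV4 (at least 9.22-fold higher) and ETV5 are missing because the vehicle array was dim. The bound was therefore judged too lenient once the value was seen. The ERK list stood at 0.55 in COM vs NaOx (percentile 99.99, 6 of 12 at least 1.5-fold higher) and at -0.45 in NaOx vs vehicle (percentile 0.13).

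The p53 targets were higher together on the NaOx array. Of the members, 61.1% (11 of 18) were at least 1.5-fold higher. As the list median was already past 1.5-fold, this share is no separate test of an error of single probes or spots. The 7 other measured probes of 5 members were all higher, with a median of 0.97, which argues against such an error for those genes. A vehicle array that stands apart is argued against by the median of -0.72 in COM vs NaOx. A second list of p53 targets, written before its values were seen, stood at 0.54 (percentile 100), with 12 of 13 members higher, so a candidate explanation is a p53 target programme on that array. HEK293T carries the SV40 large T antigen, which binds p53, and no measurement of p53 activity was analysed here. For all 3 patterns, a difference between single cultures that is not the treatment cannot be told apart from the treatment, since each group has 1 sample.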
